A study of Mus musculus with 2 samples.

How the data were processed

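Poly(A)+ RNA from the liver of C57BL/6J mouse embryos at embryonic day 18 (E18) was sequenced in 2 libraries, which the labels number as biological replicates 1 and 2 of 1 group. Per the labels, the tissue came from littermates of both sexes, RNA longer than 200 nt was kept, ribosomal RNA was depleted, spike-in RNAs were added, and stranded libraries were read as 101-nt pairs. With 1 group there was no contrast between conditions. The libraries were described together and then set against each other with 1 library on each side, so no p-value is given for any gene or list.

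The main tables were made by the authors for each library on the mouse build mm10 with the GENCODE M4 annotation, per the file headers and the deposited notes on each sample. They hold an expected count per gene, which is an estimated number of fragments in which the authors' software shared out fragments that matched several genes. The deposited TPM values are transcript abundances, scaled by each gene's effective length and to a fixed total in each library. The FPKM values deposited beside them are fragment densities per kilobase and sequencing depth and served only as an alternative. In the transcript tables, the authors give the percent of a gene's TPM that each transcript holds. The aligner, the quantifier and their versions are not given in the sources used here.

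A second set of tables covers both replicates together on the older build mm9. The deposited gene table of that set, with ENSEMBL 65 annotation, gives 2 RPKM values (read density per kilobase and sequencing depth) for each of 37310 genes, each gene standing in 2 records with equal values. The deposited junction list gives a whole read count across each splice junction for each replicate. The deposited contig list, a contig being a stretch of stranded read coverage, gives a signal for each contig over both replicates, on a scale not given in the sources used here. Both lists also carry a score from the authors, in the field where the format holds an irreproducible discovery rate. The transcript table and the assembled models of this build were not used here.

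Gene symbols, biotypes and mm10 positions were taken from GENCODE M21 by gene identifier without its version. Of 43346 mouse gene identifiers, 42462 matched and 884 did not. All coordinates are 1-based. Coordinates of junctions and contigs are in mm9 and those of genes in mm10, and none was converted. Rows that name no mouse gene (spike-ins, the phiX control and 26248 numbered short entries, which held 0 and 7 counts) were left out of library sizes. Mouse genes held 97.2% of the counts of replicate 1 and 97.9% of those of replicate 2, the spike-ins 2.79% and 2.01%, and phiX 0.0383% and 0.123%.

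Expected counts were rounded to whole numbers and scaled by TMM in edgeR 4.0.16 under R 4.3.3. DESeq2 1.42.0 size factors were the alternative. A log2 ratio of replicate 2 over replicate 1 was taken on scaled counts with 0.5 added, so it understates differences of genes with few counts. The biological coefficient of variation (BCV) is the square root of edgeR's common dispersion, over genes with at least 10 counts in both libraries. The number of genes beyond 2-fold, at a mean count of at least 50, was set beside 100 Poisson simulations at the same depths. The replicate correlation used log2(TPM + 1) over genes with a mean TPM of at least 1. A gene counted as detected at 1 TPM or more in both libraries, and a member of a gene list at a mean TPM of at least 1.

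A total of 43 gene lists (pathways, cell types, neighbouring tissues, sex-linked genes and RNA classes) were fixed before the data were examined, together with 12 gene ratios, the thresholds, most of the other settings tried and the rule for naming genes. For each list, the median log2 ratio of members with a mean count of at least 10 was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart below percentile 0.5 or above 99.5. This describes the 2 libraries and does not test a population. Of the listed symbols, 10 were not found under that spelling. The text names the 15 genes with the highest mean TPM, up to 4 members of each list by mean TPM, the genes of the ratios, the 5 highest and 5 lowest protein-coding log2 ratios at a mean count of at least 100, the 5 genes that differed most between builds, and up to 3 contigs outside exons. Some of these are not reported here. Any other gene is said to have been chosen after its values were seen.

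The list step was tested on simulated data for this pair of libraries, over 17608 genes. Of 200 random lists with no change, 1 stood apart. Each gene was simulated independently, so this is not the rate for lists whose members vary together. Of 10 lists of 20 genes, 7 stood apart when raised 1.2-fold and 10 when raised 1.5-fold. In the simulation of the 2-fold count, over 14955 genes, all 200 genes raised 4-fold were found. With the common BCV given to every gene, 33 of 14755 unchanged genes passed 2-fold. A simulated BCV of 0.1 over 17137 genes came back as 0.101, and as 0.146 when 200 genes were changed. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 and bedtools 2.31.1 did the rest.

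At these depths, counting error is small for most genes. Intervals of shares are exact (Clopper-Pearson) at 95%, and the limit for a count of 0 is 3 counts per library. Both cover counting error only, since reads carry no molecular identifiers. The SD over 2 libraries is a rough measure of spread. Alternatives covered thresholds, pseudocounts, scalings, units, builds and each replicate left out. A further 4 alternatives were added after seeing the data. In the list comparison, pancreas, gut, striated muscle and sex-linked members were left out, or the length trend was removed. The others were exons of either strand for contigs, and TPM set again without mt-Atp8 and the spike-ins.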

Results

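The data describe the poly(A)+ transcriptome of mouse fetal liver shortly before birth, a tissue that then both makes plasma proteins and produces blood cells. The 2 replicate libraries of 1 group were measured, with no second condition, age or tissue. Total expected counts were 163766625 in replicate 1 and 139889938 in replicate 2, of which 97.2% and 97.9% fell on mouse genes. At 1 TPM or more in both libraries, 12291 genes were detected. Of these, 11568 were protein coding, which is 53.9% of the 21474 protein-coding genes in the table. Protein-coding genes held 91.8% and 92.2% of all TPM. Gene positions below are on mm10.

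Haemoglobin and plasma protein mRNAs made up a large part of the RNA. The 4 adult globin genes together held 22.1% ± 0.434 of all TPM (SD, n = 2), and the 31 secreted plasma proteins of hepatocytes held 19.6% ± 0.484. The alpha-globin gene Hba-a2 (chromosome 11, 32296489 to 32297298) reached 90078 ± 3137 TPM, and the beta-globin gene Hbb-bs (chromosome 7, 103826534 to 103828096) reached 73233 ± 4810. Their neighbours Hba-a1 and Hbb-bt stood at 27512 ± 1001 and 29856 ± 1671. The split within each pair is uncertain because the copies share reads. Albumin (Alb, chromosome 5, 90460897 to 90476602), the main plasma protein of the adult, stood at 75536 ± 311 TPM. It was followed by the fetuin gene Ahsg at 22646 ± 1623, the iron carrier transferrin (Trf) at 18294 ± 592, Apoe at 13878 ± 2034 and alpha-fetoprotein (Afp, chromosome 5, 90490737 to 90508907), the fetal counterpart of albumin, at 13285 ± 860. The apolipoproteins Apoa2 and Apoa1 stood at 8271 ± 371 and 7053 ± 859, and the protease inhibitor Serpina1e, one of several near-identical copies, at 6054 ± 280. Shares of lists and of protein-coding genes are of all TPM, with the spike-ins included. Of the TPM of mouse genes alone, the 10 highest genes held 41.9% ± 2.14 and the 100 highest held 63.0% ± 1.17. One of the 10 was mt-Atp8, at 42258 ± 18206 TPM. Its effective length of 8.86 nt makes that value unreliable, since 76318 and 33457 counts were divided by it. In replicates 1 and 2, mt-Atp8 stood at 55131 and 29384 TPM and the 10 highest genes held 43.4% and 40.4%. That share and its SD therefore rest partly on mt-Atp8. The pseudogene Gm29216, at 5514 ± 40.5 TPM, was among the 15 highest and is uncertain, because a pseudogene can share reads with its parent gene.

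**Figure D1:**
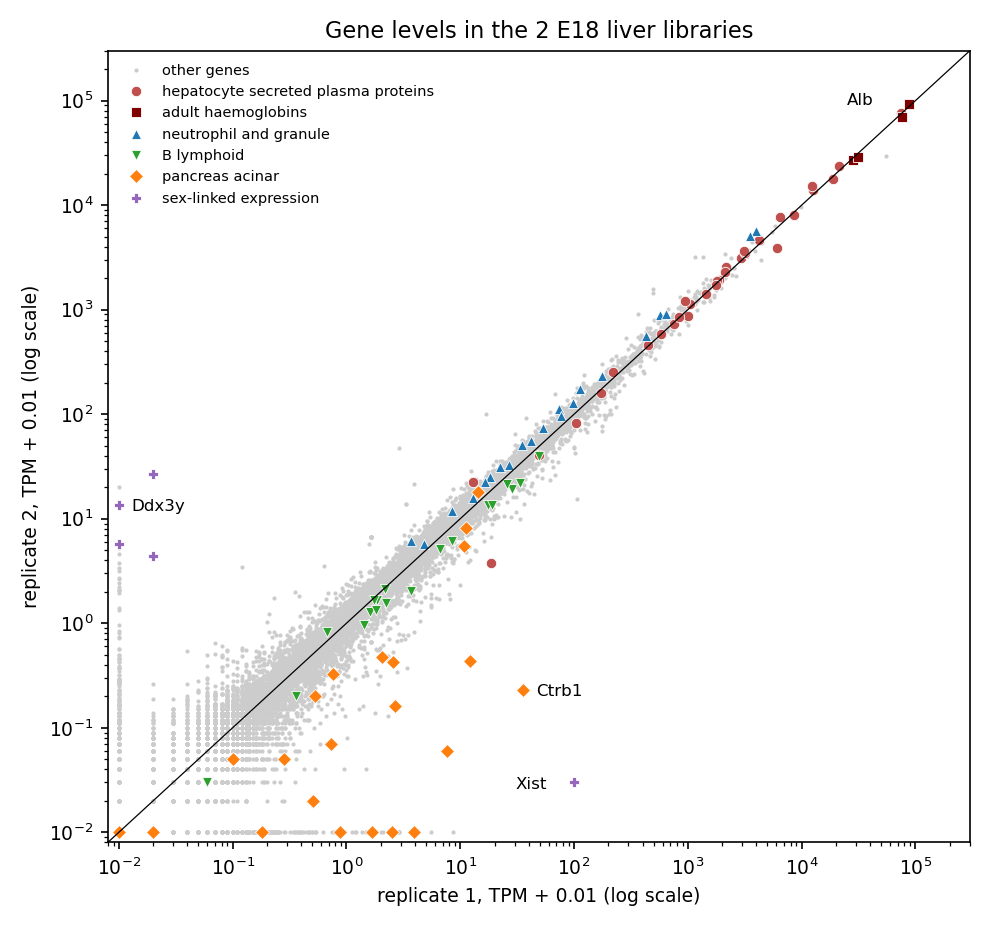
TPM of every gene in replicate 1 (horizontal) against replicate 2 (vertical), both with 0.01 added and on log scales, with members of 6 gene lists coloured and the line of equal values drawn. Haemoglobin genes and most plasma protein genes lie near the line (Apoa4, with a log2 ratio of -2.40, is an exception chosen after its value was seen), while Xist (157187 and 41 counts), Ddx3y (1 and 6544 counts) and Ctrb1 (3729 and 19 counts) lie far from it.

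Genes of most hepatocyte functions were detected. In the lists, a member was counted as detected at a mean of at least 1 TPM. All 31 secreted plasma proteins passed that level, with a median of 1835 ± 61.9 TPM, above 99.6% of the genes with a mean of at least 1 TPM. All 24 complement and coagulation factors found were detected at a median of 98.3 ± 7.24 TPM, led by C3 (1751 ± 216) and antithrombin, Serpinc1 (1470 ± 41.5). All 22 hepatocyte transcription factors were detected at a median of 17.8 ± 0.163 TPM, the highest being Cebpa at 92.3 ± 16.0. The 8 urea cycle genes had a median of 76.0 ± 1.199 TPM, with Ass1 at 497 ± 16.2 and Cps1, which makes carbamoyl phosphate, at 238 ± 11.2. Fatty acid oxidation and ketogenesis genes had a median of 129 ± 17.2 TPM over 22 members, including Acaa2 at 496 ± 32.0. Amino acid catabolism genes (19 of 20 detected) had a median of 71.7 ± 2.62 TPM. Cholesterol synthesis genes (23 of 23) had a median of 62.8 ± 4.10. Gluconeogenesis and glycogen genes (16 of 16) had a median of 55.2 ± 3.44, including Fbp1 at 720.0 ± 58.4. Bile acid genes (12 of 14) had a median of 32.1 ± 4.74, led by the bile acid importer Slc10a1 at 342 ± 29.9, and fatty acid and triglyceride synthesis genes (18 of 18) one of 35.5 ± 0.0884. Of 15 acute phase genes, 11 were detected, with haptoglobin (Hp) at 1483 ± 92.7.

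Fetal markers stood beside genes of the mature liver. All 17 fetal and oncofetal genes were detected and together held 2.66% ± 0.0745 of TPM. Besides Afp, they included the imprinted non-coding RNA H19 (chromosome 7, 142575529 to 142578143) at 9681 ± 168 TPM and the growth factor gene Igf2 at 2404 ± 60.6. Of 31 genes that rise in mouse liver after birth, 20 were detected at a list median of 15.01 ± 6.87 TPM, led by the alcohol dehydrogenase Adh1 at 933 ± 10.1. Afp stood at 0.176 ± 0.0107 of the Alb level (n = 2), and at 0.466 in the mm9 table. Igf2 exceeded Igf1, its postnatal relative, 155 ± 42.8 times (124 and 185 in the 2 libraries), and 359 times in the mm9 table. The pyruvate kinase gene Pkm exceeded Pklr, the liver and red blood cell gene, by a ratio of 1.44 ± 0.00943 in the whole tissue. The fetal cytochrome Cyp3a16 stood at 2.02 ± 0.206 times Cyp3a11. The glucose transporter ratio Slc2a1 to Slc2a2 was 1.10 ± 0.252. Of 28 imprinted genes, 24 were detected, including Meg3 at 551 ± 165 TPM and Rian at 426 ± 51.4.

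Erythroid genes of the definitive lineage were high, and the embryonic globins Hbb-y, Hbb-bh1 and Hba-x were low. The embryonic beta-like genes Hbb-y and Hbb-bh1 together stood at 0.000107 ± 1.46e-05 of the adult Hbb-bs and Hbb-bt, and Hba-x stood at 3.09e-05 ± 4.19e-06 of the adult alpha genes. Another member of the embryonic list, the theta-like globin gene Hbq1b, stood higher, at 81.1 ± 6.54 TPM. The ratio of alpha-like to beta-like globin transcripts was 1.14 ± 0.0926 by TPM but 0.735 by counts without length scaling, so its direction depends on the scaling. All 35 erythroid membrane and regulator genes found were detected, with a median of 57.8 ± 2.40 TPM. The anion exchanger Slc4a1 stood at 265 ± 3.50 TPM. All 12 haem synthesis genes were detected at a median of 123 ± 7.95 TPM, led by Alas2, the erythroid first step, at 474 ± 1.09. The erythroid factor Gata1 exceeded the progenitor factor Gata2 by a ratio of 43.8 ± 4.03, which was 24.7 by counts without length scaling and 29.5 in the mm9 table. Iron handling genes (16 of 19) had a median of 50.6 ± 5.37 TPM.

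Genes of other blood lineages were also detected, at list medians that depend on the genes listed and do not rank the lineages by abundance. All 21 neutrophil genes found were detected at a median of 63.3 ± 14.2 TPM, with the calprotectin genes S100a8 and S100a9 at 4784 ± 1188 and 4308 ± 1121. Macrophage and Kupffer cell genes (21 of 22) had a median of 31.2 ± 3.48 TPM, led by the lysozyme gene Lyz2 at 480.1 ± 70.3. Megakaryocyte and platelet genes (18 of 18) had a median of 10.8 ± 1.46, with the platelet factor Pf4 at 210 ± 5.71. Stem and progenitor genes (15 of 21) had a median of 4.41 ± 0.106. B lymphoid genes (16 of 19) had a median of 2.14 ± 0.113, with the immunoglobulin heavy chain gene Ighm at 44.5 ± 6.63. Mast cell, basophil and eosinophil genes (9 of 17) had a median of 1.88 ± 0.396, although Prg2 stood at 97.3 ± 28.3 and Ear2 at 65.8 ± 13.3. Only 5 of 18 T and natural killer cell genes reached a mean of 1 TPM.

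Among structural cell types, 25 of 25 endothelial genes were detected at a median of 12.5 ± 0.361 TPM and 23 of 24 stellate and mesenchymal genes at 11.6 ± 1.01. Cholangiocyte genes (12 of 18) had a median of 2.63 ± 0.0778 and mesothelial genes (8 of 11) one of 1.63 ± 0.0778. Of the neighbouring tissues, 11 of 23 pancreas acinar genes, 11 of 23 striated muscle genes, 4 of 19 gut genes, 3 of 15 adrenal genes and 1 of 18 lung and kidney genes reached a mean of 1 TPM. By library, 12 acinar and 13 muscle genes were at 1 TPM or more in replicate 1, and 3 and 8 in replicate 2. All 28 proliferation genes were detected at a median of 42.96 ± 0.0707 TPM, above 86.0% of expressed genes, with the replication clamp Pcna at 158 ± 7.92 and the cell cycle kinase Cdk1 at 133 ± 0.325. Cytosolic ribosomal protein genes had a median of 773 ± 62.2 TPM, mitochondrially encoded mRNAs one of 1829 ± 162, hypoxia targets one of 17.4 ± 2.23 and immediate early genes one of 5.93 ± 1.97.

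**Figure D2:**
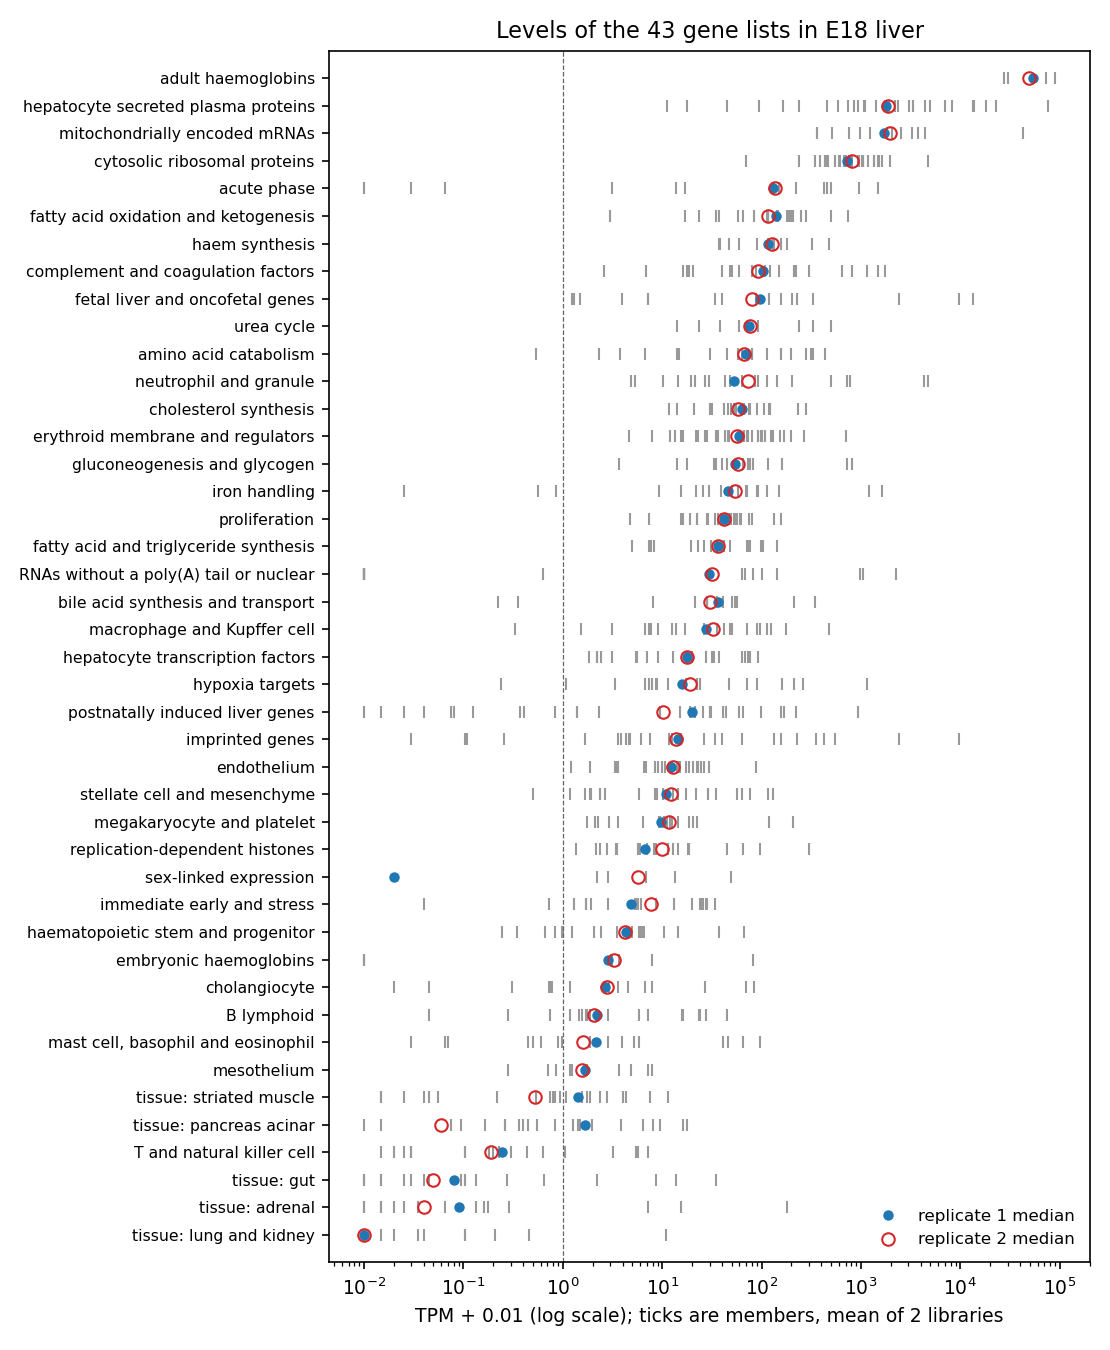
Levels of the 43 gene lists in TPM + 0.01 on a log scale, ordered by list median, with a tick for each member (mean of 2 libraries) and a circle for the median in each replicate; the dashed line marks 1 TPM. Adult haemoglobins (22.1% of TPM) and secreted plasma proteins (median 1835 TPM) lie near the top, and the gut, adrenal and lung and kidney lists at the bottom.

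The 2 replicates were compared next, which shows how far livers of the same labels differed. Across 12557 genes, log2(TPM + 1) correlated with Pearson's r = 0.988 and Spearman's rho = 0.985, although genes are not independent replicates. The BCV was 0.141 over 17137 genes, and 0.219, 0.125 and 0.115 among genes of low, middle and high expression when these were split into 3 groups of equal size. Of 14955 genes, 273 (1.83%) differed beyond 2-fold. Poisson sampling alone, which covers counting error and no difference between tissue samples, gave a mean of 0.3. A simulation with a BCV of 0.141 for every gene put 33 of 14755 unchanged genes beyond 2-fold. This simulation does not carry the wider spread of low genes (0.219) and can understate how many pass without a change. It can also overstate that number, because the BCV of 0.141 comes from the same 2 libraries and can be raised by genes that differ. In simulated data, 200 changed genes moved a BCV of 0.1 to 0.146. Of the 273 genes, 52 were higher and 221 lower in replicate 2. On the TPM ratio the split was 89 and 177. TPM also moved the median log2 ratio of all genes to 0.10, against -0.00 after TMM. The log2 ratio went with effective length (Spearman's rho = 0.231 over 17608 genes), with medians from -0.06 in the shorter to 0.11 in the longest of 10 groups of protein-coding genes with at least 100 counts.

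Of the 43 lists, 15 stood apart between the libraries, 4 higher and 11 lower in replicate 2. Lists of genes drawn independently would give 0.43. Genes of a cell type or pathway can shift together, so 0.43 is not the rate for such lists. Neutrophil genes were higher in replicate 2 in 21 of 21 cases, with a median log2 ratio of 0.34. S100a8 was higher by 0.33, the granule genes Ngp by 0.37 and Camp by 0.51. Replication-dependent histones, whose mRNAs mostly lack a poly(A) tail, were higher in 21 of 21 cases (median 0.26), as were 8 of 9 RNAs that lack a tail or stay in the nucleus (median 0.53), such as Rn7sk, a nuclear RNA that restrains transcription elongation (24439 and 43723 counts). Proliferation genes showed no such difference, with a median of -0.03 at percentile 24.5. B lymphoid genes were lower in replicate 2 in 19 of 19 cases (median -0.53), with the surrogate light chain genes Vpreb1 at -0.68 and Vpreb3 at -0.73. T and natural killer cell genes were lower in 13 of 14 (median -0.64), among them the granzyme Gzma at -0.99. That list did not stand apart on the TPM ratio, at percentile 0.85.

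Lipid metabolism genes were also lower in replicate 2. Cholesterol synthesis genes were lower in 21 of 23 cases with a median log2 ratio of -0.33, including Insig1 at -0.65, Fdps at -0.49 and Sc5d at -0.92. Fatty acid and triglyceride synthesis genes were lower in 14 of 18 (median -0.30), with the fatty acid synthase Fasn at -0.45 but Dgat2 at 0.16. Bile acid genes were lower in 12 of 14 (median -0.33), with the exporter Abcb11 at -0.47 and Slc27a5 at -0.75. Genes that rise after birth were lower in 22 of 26 (median -0.51), with Rdh7 at -0.41 and, in the other direction, Selenbp2 at 0.62. Cholangiocyte genes were lower in 13 of 17 (median -0.29), with osteopontin (Spp1) at -0.63. Iron handling genes were lower in 13 of 18 (median -0.18). Fatty acid oxidation genes were lower in 16 of 22 (median -0.15), but that list did not stand apart on the TPM ratio (percentile 0.93) or with the length trend removed (percentile 1.64). Pancreas acinar and striated muscle genes, described next, were lower in the same library as these lists. Gut genes were lower in 7 of 8 (median -0.43, percentile 0.58) but did not stand apart. Neither did lung and kidney genes (median -0.53, percentile 3.09) or adrenal genes (median -0.09, percentile 34.7). Secreted plasma proteins (median -0.05, percentile 42.1), erythroid genes (-0.02, percentile 55.2), haem synthesis genes (-0.05, percentile 35.5) and hepatocyte transcription factors (-0.00, percentile 41.0) did not stand apart. Some other hepatocyte lists inside the limits leaned lower in replicate 2. Complement and coagulation genes were lower in 22 of 24 (median -0.12, percentile 0.99) and stood apart on the TPM ratio. Urea cycle genes were lower in 7 of 8 (-0.17, percentile 2.17) and gluconeogenesis and glycogen genes in 10 of 16 (-0.09, percentile 9.06). Amino acid catabolism genes (-0.07, percentile 19.8) and acute phase genes (-0.10, percentile 21.5) lay nearer the middle.

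**Figure D3:**
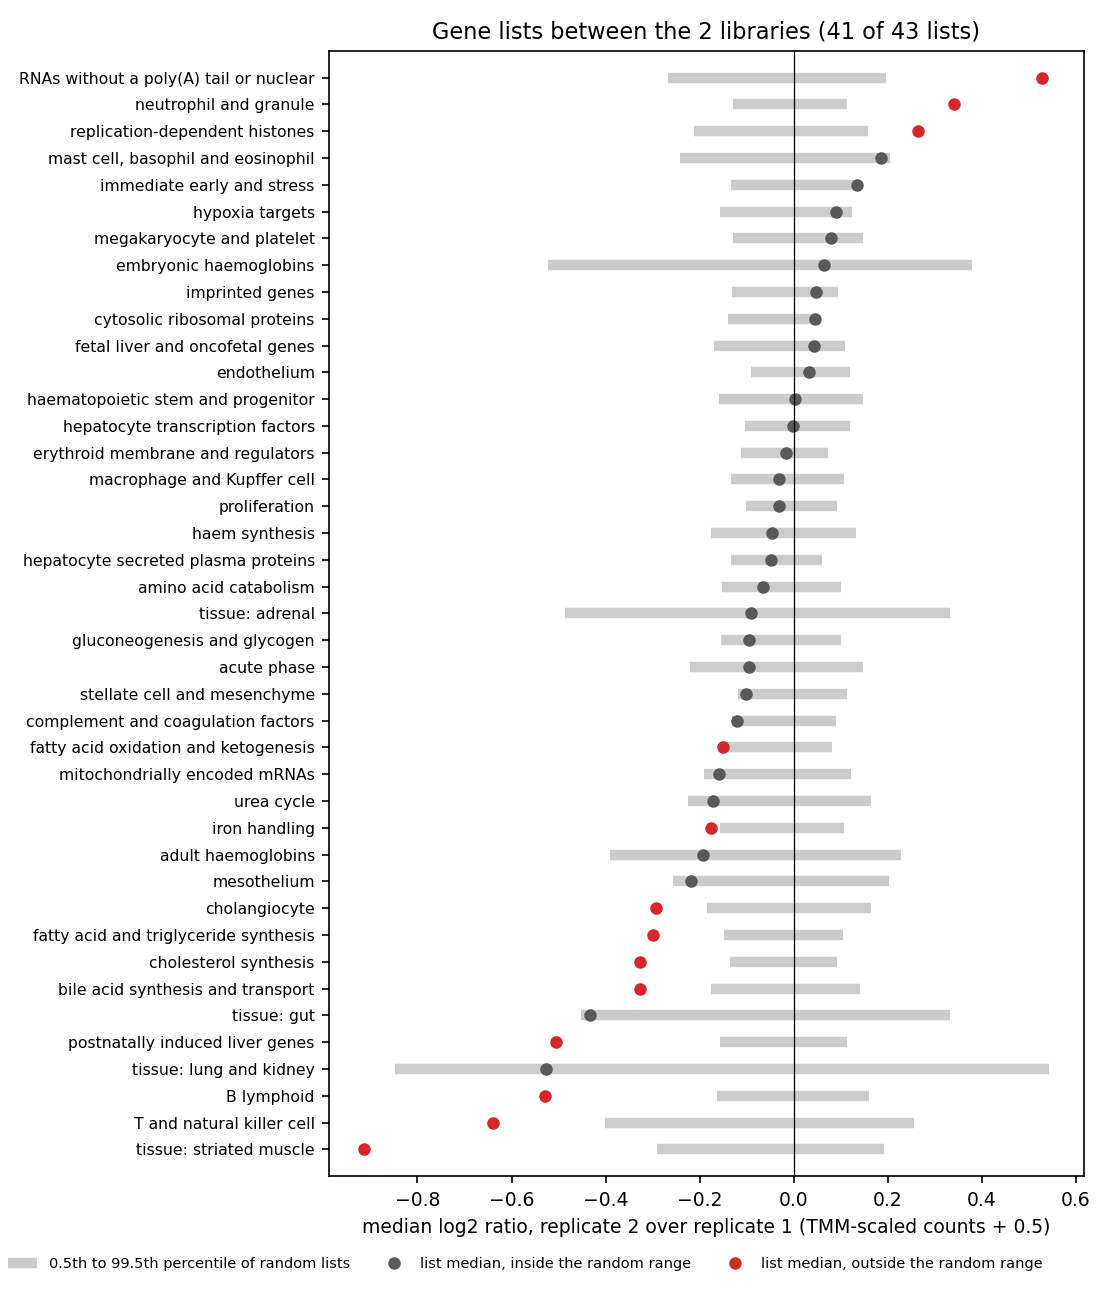
Median log2 ratio of replicate 2 over replicate 1 (TMM-scaled counts with 0.5 added) for 41 of the 43 lists, as points, with grey bars for the range of medians of 10000 random lists matched on expression, bounded by the percentiles beyond which a list stands apart. Points in red lie outside the bars, from striated muscle at -0.91 to RNAs without a poly(A) tail at 0.53; the pancreas acinar (-3.86) and sex-linked (10.87) lists are left out for scale.

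Most digestive enzyme genes of the pancreas were far higher in replicate 1. Of 20 acinar genes with enough counts, 19 were lower in replicate 2, with a median log2 ratio of -3.86, or -3.66 with members under 3 counts set at 3. The chymotrypsinogen gene Ctrb1 (chromosome 8, 111686519 to 111691010) had 3729 and 19 counts, a 171-fold difference after scaling. The elastase gene Cela2a had 984 and 5 counts and the lipase gene Cel 456 and 1. The trypsinogen genes Prss2 (365 and 0 counts) and Try5 (226 and 0) were at least 108-fold and at least 67.3-fold lower in replicate 2, against a limit of 3 counts. By contrast Cela1, with 1977 and 2050 counts, had a log2 ratio of 0.22, and Pnliprp1 (2434 and 1451 counts) and Amy2a5 (2511 and 1056, uncertain because copies share reads) differed less, at -0.58 and -1.08. Striated muscle genes were lower in 17 of 20 cases (median -0.91), including Mylpf at -0.75 and, in the other direction, the troponin gene Tnnc1 at 0.84.

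Sex-linked genes stood apart most, with a list median of 10.87, or 10.42 with members under 3 counts set at 3. Xist, the RNA that silences 1 X chromosome in female cells, had 157187 counts in replicate 1 and 41 in replicate 2, where it stood at 0.0293% of the other library after scaling (95% interval 0.0210 to 0.0397). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 8 counts in replicate 1 and 18351 in replicate 2, or 0.0389% (0.0168 to 0.0766). The labels describe both sexes as pooled. Hist2h3c1, also among the 5 highest ratios at 0.07 and 557 counts, shares reads with near-identical histone copies and its value is uncertain.

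Transcript use was similar in the 2 libraries. Among 4251 genes of at least 10 TPM with 2 or more transcripts, 1086 (25.5%) drew at least 90% of their TPM from 1 transcript in both libraries and 897 (21.1%) under 50%. The same transcript led in 4046 (95.2%). Pkm-201 held 95.8% ± 0.0212 of Pkm, and the leading transcript of Igf2 held 40.5% ± 0.0495. Bag1, a co-chaperone gene chosen after its values were seen, had different leaders, with Bag1-202 at 71.1% in replicate 1 and 21.01% in replicate 2.

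The gene values of the 2 builds were compared next; the builds differ in genome, annotation and unit at once. Across 12586 genes, mean TPM on mm10 and mean RPKM on mm9 gave Spearman's rho = 0.826, and 854 genes differed over 4-fold after centring. Among protein-coding genes rho was 0.929 with 262 such genes. The 5 most different genes were mt-Atp8, mt-Co1, mt-Co2, mt-Co3 and mt-Cytb, all listed at 0 on mm9. The other mitochondrially encoded mRNAs of the gene list, such as mt-Atp6 (2046 TPM on mm10), were also at 0 there. These differences thus show that the mm9 values hold no mitochondrial mRNA. In the mm9 gene table some adult globin genes were far lower in 1 replicate column than in the other, so the ratios with globins above are given from mm10.

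Splicing and coverage outside the annotation were read from the mm9 lists. Of 1077149 junctions, 288031 (26.7%) had reads in both replicates. The 176210 junctions that carry the mark A=1 in the list, all of which joined annotated exon ends, held 92.2% of junction reads, and 90.2% of them had reads in both replicates. Of the rest, 17066 had at least 10 reads in each replicate. Of 677743 contigs, 80.8% did not overlap an exon of the same strand, but they held 5.94% of the length-weighted signal. Of these, 336806 lay in introns and 211007 between genes. With a score under 0.1, the contigs outside exons of either strand with the highest signal were at chromosome 3, 5860318 to 5860829 (512 nt, signal 4010), chromosome 11, 108872946 to 108873445 (500 nt, 2430), both between genes, and chromosome 17, 71312985 to 71313245 (261 nt, 2190), within a gene. Joining these 2 filters to pick contigs was decided after the values were seen, and the list gives no value per replicate. Spike-in RNAs took 2.79% and 2.01% of counts, a ratio of 1.39. Of 96 spike-ins, 84 and 79 had a count above 0, and 70 had at least 10 counts in both libraries.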

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

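Of the tests in this part, the test of genes that escape X inactivation and the test of endocrine pancreas genes were written before their results were seen, and the other 6 were chosen only after the result was seen.

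Xist was found in replicate 1 and Y-linked RNA in replicate 2, although the labels pool both sexes. Like shares of both sexes in each library are argued against by the Y-linked count of replicate 1, at 0.0389% of that of replicate 2. That count is part of the pattern itself and is no separate evidence. Read assignment on mm10 is argued against by the mm9 junction list, where Y-linked junction reads were 39 and 13471, or 0.290%. A candidate explanation is that each library came from embryos of 1 sex, and the genes Kdm6a, Kdm5c, Eif2s3x and Ddx3x, which escape X inactivation and so are higher in female cells, were lower in replicate 2 in 4 of 4 cases with a median log2 ratio of -0.45 (percentile 0.06 of matched random lists). Sex, replicate and any carry-over of tissue cannot be separated with 1 library each, so every difference between the replicates shares this limit.

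Pancreas acinar RNA was higher in replicate 1 (Ctrb1 3729 and 19 counts, Cela2a 984 and 5, Cel 456 and 1). Read assignment on mm10 is argued against by Ctrb1 junction reads on mm9, which differed 176-fold (3688 and 21). A candidate source is pieces of pancreas in the tissue of replicate 1, and the endocrine genes Ins1, Ins2, Gcg, Iapp, Pyy and Sst together had 288 and 29 counts, 8.86 times as many after scaling, only just above the 8 set beforehand. The insulin genes Ins1 and Ins2 had 56 and 100 counts against 0, while Pyy (44 and 12) and Sst (39 and 15) differed less. Of the 23 acinar genes, 12 reached 1 TPM in replicate 1 and 3 in replicate 2, and of the 20 with enough counts only Cela1 (1977 and 2050 counts) was not lower in replicate 2; expression of acinar genes by liver cells of replicate 1 was not tested and stays open.

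In the mm9 gene table, which the main comparisons do not use, Hbb-bt had an RPKM of 15842 in 1 replicate column and 0 in the other. Hbb-bs (25053 and 65.1) and Hba-a1 (27371 and 562) showed the same pattern, and Hba-a2 (32579 and 32486) did not. Missing globin RNA in 1 library is argued against by junction reads of both replicates, the lower never under 68.1% of the higher for the 3 genes. For a limit on the deepest genes, 6 other nuclear genes with more reads than Hba-a1, such as Alb and Afp, differed under 2-fold. A limit that lowers both columns alike cannot be seen that way. Alb had 21405199 and 17784151 counts on mm10, against 3687365 and 3338512 for Afp, at effective lengths of 1823 and 1866 nt. On mm9 the RPKM of Alb was 5420 and 4295, against 2315 and 2165 for Afp, so such a limit stays open. Reads moved between copies are argued against by a summed adult globin RPKM that differed 3.05-fold. What lowered these values in 1 column stays open.

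The phiX control sequence, which belongs to no mouse gene, had 62647 counts in replicate 1 and 172525 in replicate 2 (0.0383% and 0.123% of counts).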

How the results depend on the processing

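Alternatives added only after the result was seen were the left-out list members, the removed length trend, exons of either strand and the TPM set again without mt-Atp8 and the spike-ins; all others were planned. No called list changed sign in the 6 alternatives of the list comparison, which put 12 to 18 lists apart. DESeq2 size factors kept all 15. The TPM ratio kept 13, losing fatty acid oxidation and T and natural killer cell genes and gaining complement and ribosomal protein genes. A mean count of at least 50 kept 15 and added mast cell, gut and immediate early genes, and matching on length kept 15 and added mast cell, stellate and immediate early genes. Removing the length trend kept 14, losing fatty acid oxidation and adding gut, immediate early and ribosomal protein genes. Leaving out pancreas, gut, striated muscle and sex-linked members kept 12. Those 12 share no member with the genes left out and could not change, so this setting says nothing about their stability. The other 3 had no members left by construction. The mm9 RPKM ratio of lists was not run, because the columns of that table name no library and none was assigned from their values.

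With a minimum of 5 TPM, 7927 genes were detected, fewer by construction. Among mouse genes alone, the 10 highest held 29.0% of TPM without haemoglobins and 32.9% of counts. The replicate correlation was 0.978 with a pseudocount of 0.1, 0.996 with no minimum, 0.986 from 5 TPM and 0.947 on mm9. Genes beyond 2-fold numbered 772 from 10 counts, 134 from 200 counts and 174 among protein-coding genes. The BCV was 0.121 from 100 counts, 0.162 with no minimum, 0.125 for protein-coding genes and 0.193 from DESeq2. The secreted plasma protein list stood at percentile 99.7 on mm9, 99.8 by counts without length scaling, 99.7 among protein-coding genes and 99.7 from 0.1 TPM, and at 99.62 to 99.65 with a replicate left out. Erythroid genes stood at 87.3 on mm9, 91.7 by counts without length scaling and 92.1 from 0.1 TPM. Proliferation genes stood at 78.9, 87.0 and 89.6 under those settings, and at 85.6 to 86.0 with a replicate left out.

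Afp to Alb was 0.466 on mm9. Embryonic to adult beta globins stood at 8.65e-05 by counts and 0.0123 on mm9, where adult beta globins were far lower in 1 column. Among other ratios, Igf2 to Igf1 was 359 on mm9, Gata1 to Gata2 was 24.7 by counts and 29.5 on mm9, and alpha-like to beta-like globins was 0.735 by counts; its mm9 value is left out because beta globins were far lower in 1 column. Genes with 1 leading transcript numbered 2142 from 1 TPM, 412 from 50 TPM and 1648 at 80%. The correlation of the builds was 0.693 from 10, 0.929 for protein-coding genes and, for single columns, 0.7997 and 0.834 with replicate 1 of mm10 and 0.806 and 0.818 with replicate 2. Junctions in both replicates with at least 10 reads numbered 183165. Contigs outside exons were 66.6% with a score under 0.1, 90.8% when most of the contig had to overlap and 78.9% for exons of either strand. Over all alternatives, 143 of the list level values moved by more than the spread between replicates and 158 by less, and among ratios 17 and 43. A ratio is a mean of 2 libraries, and leaving out a replicate always moves it by less than their SD. Such cases therefore show no stability. The cause was not tested for these values unless stated. Lists of low genes rest on few members, such as lung and kidney with 5 usable members.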

Other observations

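No test was run in this part, and the genes of its first paragraph were chosen only after their values were seen.

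Macrophage genes as a list did not differ between the libraries (median log2 ratio -0.03), but its members went both ways. The Kupffer cell lectin Clec4f was lower in replicate 2 by a log2 ratio of -1.05 (17470 and 7500 counts), and Vsig4 stood at -0.58, whereas the scavenger receptor Marco stood at 1.00 (7894 and 14120 counts). Cd5l, at -0.07, and Timd4, at 0.07, were alike. In lipid synthesis, Thrsp stood at -2.19 (1319 and 257 counts) and the desaturase Scd1 at -1.15, while their regulator Srebf1 stood at 0.00. Among secreted proteins, Apoa4 stood at -2.40 and transthyretin (Ttr) at -0.76, beside Serpina6 at 0.69. Hepcidin (Hamp), the iron hormone, had 873 and 432 counts. Cyp8b1 stood at -0.95, whereas Cyp7a1, the first enzyme of the main bile acid pathway, stood at 0.17.

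The numbering of replicates in the mm9 gene table ran opposite to that of the mm10 tables in these values. Across 13438 genes, the log2 ratio between the mm9 columns correlated with that between the mm10 libraries at a Pearson's r of -0.628 and a Spearman's rho of -0.560. Xist had an RPKM of 0.0362 and 27.0 in mm9 columns 1 and 2, against 157187 and 41 counts on mm10, while its mm9 junction reads were 8758 and 1. No column was reassigned, and no result above rests on which mm9 gene column is which library.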
